A study of Homo sapiens with 10 samples.

How the data were processed

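RNA sequencing was measured in 10 libraries of 2 human prostate cancer cell lines. Per the labels' protocols, total RNA was taken from plated, untreated cells, 1 µg per sample went into a stranded poly(A) library kit, and paired reads of 100 bases were sequenced with a plan of 2 × 26M reads per sample. Per the submitters' processing notes, DRAGEN, Picard and DESeq2 were used with genome build hg38, without versions or the role of each.

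The authors deposited a single table of 37361 gene symbols by 10 libraries with decimal commas. Its values were taken as TPM, transcript levels scaled to the same total in every library, from the table's layout and from column totals of 999248 to 999538 in the deposited values, a unit listed under other kinds of value because of the decimal commas. TPM keeps no sequencing depth, so the depth behind each deposited value is unknown here and no counting interval or floor was given. Values carry at most 3 decimals, and 7389 genes are listed at 0 in all 10 libraries. Every column of values was matched to a sample by its name. The libraries were grouped by their titles. For the third knockout library the genotype field names Ripk3 and the title names the knockout, and the title was followed. The labels call the samples biological replicates. The titles do not say whether the libraries of a modified group come from a single modified clone or from several. The p-values below measure the spread between libraries, which need not be that between independent knockouts or overexpressing clones. Samples of a group correlated at 0.9869 to 0.9916 across genes, and no pair held the same values throughout.

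A count model had been chosen before the data were examined, for a table of counts. Because the table holds TPM, the fallback written with it was used: limma 3.58.1 in R 4.3.3 with an intensity trend and robust variance, on log2(TPM + 1), with all 10 libraries in 1 fit of 4 groups. Genes with at least 1 TPM in at least 2 libraries were tested, plus TRPV6, which gave 14541 genes. A change was called at a Benjamini-Hochberg adjusted p under 0.05. All log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The comparisons were knockout minus wild type in PC-3M, overexpression minus unmodified in PC3M-Luc-C6, the difference between the lines in the change from lower to higher labelled TRPV6, and unmodified PC3M-Luc-C6 minus wild-type PC-3M. The 37 gene lists were fixed before the data were examined, and lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Overlaps were tested with Fisher's exact test, two-sided.

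Genes were named by a rule fixed before the data were examined. It takes TRPV6, TRPV5 and RIPK3, and in each comparison the 8 largest rises and 8 largest falls among called protein-coding genes with at least 5 TPM in the higher group and no overlap between the groups' libraries. It adds up to 2 risen and 2 fallen members of each list with at least 3 called members, and up to 5 genes for each opposite direction of the overlap. After the values were seen, list members were kept only for lists called by camera and for the 4 calcium lists, and ATF4, ASNS, TRBC2, TRBC1 and EPHB6 were added. A few genes that the rule names are not reported here, and no other gene took their place. Coordinates are those of GENCODE version 44 on hg38, matched by symbol for 25923 genes. How DRAGEN divided reads between near-identical copies is not given in the sources used here. The values of SPANXA1 and SPANXA2, the GAGE family, and TRBC1 and TRBC2 are therefore uncertain. Its division of reads between the paralogs TRPV6 and TRPV5 is not given either.

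The fit was tested on simulated data with known changes. The changed genes were drawn only from genes with a higher mean TPM than the filter asks for, and the noise was independent between genes. Recovery of lower genes or of grouped changes was therefore not tested. Only 50 genes were changed at each size, and all groups otherwise shared the same expected levels. In the real knockout comparison 44.65% of tested genes were called, and recovery at such a share was not tested either. In the PC-3M comparison 80% of genes changed by 0.5 on the log2 scale and 88% of those changed by 1 were recovered, with 6 unchanged genes called among 14088 tested genes. In the PC3M-Luc-C6 comparison these shares were 46% and 84%, with 3 unchanged genes called among 14095 tested genes.

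The alternatives were median-of-ratios scaling of the TPM values, no filter, a pseudocount of 0.1, each line alone, the replicate number as a block, an estimated correlation, a 2-fold minimum and each library left out in turn. Chosen after seeing the data were a rescaling without mitochondrial and structural RNA genes, a fit without the 2 PC3M-Luc-C6 libraries high in 5_8S_rRNA, and a fit with that rRNA class as a term. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.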

Results

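Gene expression was measured by RNA sequencing in PC-3M, a metastatic derivative of the PC-3 prostate cancer line, and in PC3M-Luc-C6, a luciferase-expressing derivative of PC-3M. TRPV6 encodes a calcium-selective channel of the plasma membrane. PC-3M was represented by 3 wild-type libraries and 3 libraries labelled TRPV6 knockout, and PC3M-Luc-C6 by 2 unmodified libraries and 2 labelled TRPV6 overexpression. Between 12847 and 13831 genes reached 1 TPM per library. The first principal component, with 45.8% of the variance, separated the lines, and the second, with 30.4%, separated the knockout from the wild-type PC-3M libraries.

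The targeted gene did not check the labels. TRPV6 (chromosome 7, 142871208 to 142885745, minus strand, hg38) was listed at 0 in all 3 wild-type PC-3M libraries and at 0.054, 0.015 and 0.086 TPM in the libraries labelled knockout. It stood at 0 and 0.004 TPM in unmodified PC3M-Luc-C6 and at 0.036 and 0.016 TPM in the libraries labelled overexpression. Neither difference passed the test (adjusted p = 0.67 and 0.94, limma). Its paralog TRPV5 was listed at 0 except for 0.021 and 0.027 TPM in the overexpression libraries, and RIPK3, named in the genotype field of the third knockout library, was listed at 0 in all 10. The directions below therefore rest on the labels alone.

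The first comparison asked how PC-3M cells labelled TRPV6 knockout differed from wild type. LCN2, which encodes the iron-siderophore-binding protein lipocalin 2 (chromosome 9, 128149071 to 128153453), rose from 1.66 ± 0.638 to 1425 ± 261.6 TPM (SD, n = 3 and 3), a log2 fold change of 9.08 ± 0.191 (SE; adjusted p = 5.55e-10). Complement component C3 rose from 0.509 ± 0.383 to 159 ± 32.2 TPM, the growth factor IGF2 from 0.0513 ± 0.0401 to 44.8 ± 2.76 TPM, and the ubiquitin ligase gene TRIM31 and the syntaphilin gene SNPH by 6.13 and 4.66 on the log2 scale. In the other direction the vitamin B12-binding protein gene TCN1 stood at 65.2 ± 6.38 TPM in wild type and was listed at 0 in every knockout library. PHACTR3 went from 180 ± 3.68 to 1.53 ± 0.25 TPM and the trefoil factor gene TFF3 from 79.6 ± 14.7 to 1.18 ± 0.214 TPM. SPANXA2, a cancer testis gene with a near-identical copy, went from 636 ± 19 to 0.286 ± 0.257 TPM, and SPANXA1 and GAGE2E had log2 fold changes of -5.26 and -5.25. GAGE12F and GAGE12G stood at 46.6 ± 10.7 and 30.3 ± 11 TPM in wild type and were listed at 0 in every knockout library, and the values of these 5 genes are uncertain because of their copies.

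Genes of inflammatory signalling rose together in the knockout libraries. Of 25 tested cytokine and NF-kB target genes 16 rose and 2 fell (17 and 3 adjusted over the list alone), with a median log2 fold change of 1.47 (camera adjusted p = 1.67e-06; adjusted p = 0.30 with an estimated correlation). The chemokine genes CCL20, CXCL6 and CXCL1 rose by 5.97, 4.85 and 6.12, while CCL2 and the adhesion receptor gene ICAM1 fell by 3.38 and 1.17. Of 16 antigen presentation genes 13 rose and none fell (14 adjusted over the list alone; adjusted p = 8.55e-07, and 0.23 as the adjusted p with an estimated correlation), among them HLA-B, which rose by 1.49 to 41.3 ± 3.7 TPM, and the immunoproteasome subunit gene PSMB8, by 1.19.

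The integrated stress response list, whose genes are induced through ATF4, fell. Of 24 tested members 18 fell and none rose, also when adjusted over the list alone, with a median of -1.03 (adjusted p = 2.38e-07; adjusted p = 0.36 with an estimated correlation). NUPR1 went from 141 ± 24.9 to 25.2 ± 2.45 TPM and SESN2 from 19.8 ± 2.17 to 4.86 ± 0.631 TPM. ATF4 and the asparagine synthetase gene ASNS, chosen after their values were seen, fell by 1.00 and 2.76. Cholesterol synthesis genes fell as well, 19 of 25 against 1 that rose (21 and 1 adjusted over the list alone; adjusted p = 4.83e-06, and adjusted p = 0.59 with an estimated correlation). The regulator gene SREBF2 fell by 0.77 and the lanosterol synthase gene LSS by 1.08, while PMVK rose by 0.19, a call lost without any 1 of 8 libraries, all but wild-type and knockout library 3 of PC-3M (adjusted p up to 0.15), and also lost without the filter, with each line fitted alone or with a term for 5_8S_rRNA classes (adjusted p = 0.082, 0.080 and 0.058).

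Adhesion genes moved in both directions. Of 25 epithelial adhesion genes 13 rose and 4 fell (14 and 5 adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.36 with an estimated correlation). EPCAM went from 86.6 ± 2.47 to 204 ± 29.5 TPM and the keratin gene KRT7 rose by 1.82, while CLDN4 fell by 0.31. Of 13 integrin genes 8 fell and 1 rose, also over the list alone (adjusted p = 0.024, adjusted p = 0.36 with an estimated correlation, and adjusted p = 0.059 without knockout library 3): ITGB1 fell by 0.90 and ITGB8 by 1.76, and ITGA5 rose by 0.64. In the hypoxia and glycolysis list 12 of 29 genes rose and 1 fell, also over the list alone (adjusted p = 0.0066, and adjusted p = 0.83 with an estimated correlation). The carbonic anhydrase gene CA12 and the phosphofructokinase gene PFKP rose by 0.75 and 0.51, and the fallen gene was VEGFA, by 0.98. Ribosomal protein genes were lower in 23 of 32 cases (24 adjusted over the list alone), with a small median of -0.16 (adjusted p = 0.00016, and adjusted p = 0.59 with an estimated correlation). RPL10 and RPS6 fell by 0.61 and 0.64. After median-of-ratios scaling 12 of the 32 were lower and the median was -0.08. RPL10 and RPS6 lie in windows of 25 neighbouring genes, described below, with 17 and 20 genes lower and 0 higher. The window medians were -0.36 and -0.53.

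Calcium-handling lists were not shifted as a whole. Of 22 calcium entry and store release genes 6 rose and 8 fell, also over the list alone (adjusted p = 0.71). The store-operated channel gene ORAI1 went from 40.5 ± 3.14 to 81.5 ± 3.27 TPM and P2RX5 rose by 0.47, whereas PIEZO2 and the IP3 receptor gene ITPR2 fell by 2.36 and 1.36. Among 18 extrusion and buffering genes 6 rose and 4 fell, also over the list alone (adjusted p = 0.41). CALB2 rose by 1.52, and the sodium-calcium exchanger gene SLC8A1 and CALM3 fell by 1.64 and 0.39. Of 19 calcineurin and NFAT genes 7 rose and 5 fell (7 and 6 adjusted over the list alone; adjusted p = 0.74), with RCAN2 lower by a log2 fold change of -3.28, NFATC2 by one of -1.29, and HOMER2 and TNFRSF9 higher by 0.65 and 1.03. Of 10 TRP channel genes 2 fell, also over the list alone (adjusted p = 0.40).

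Across the genome 6492 of 14541 genes (44.65%) passed the test, 2822 higher and 3670 lower, and 838 of them changed at least 2-fold. After median-of-ratios scaling, which moved the median of all genes from -0.06 to 0.0043, the split was 3545 higher and 2956 lower, so the direction of small changes depends on the scaling.

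**Figure D1:**
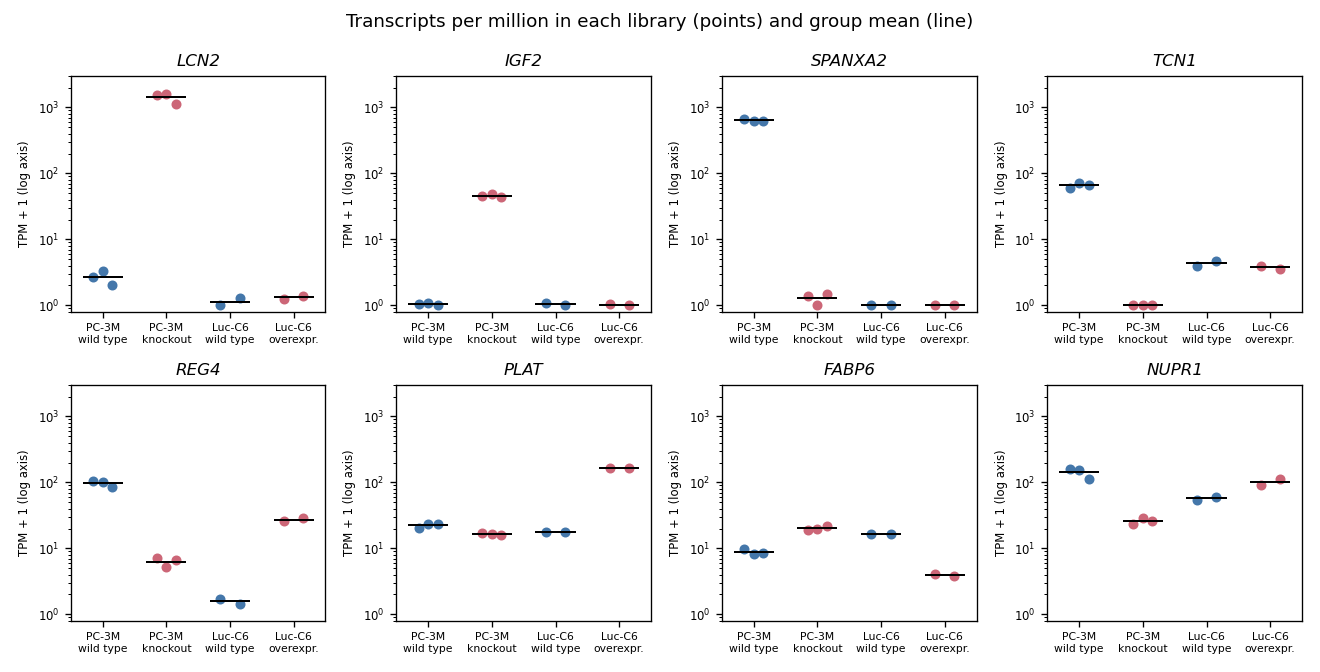
Each panel plots 1 gene in the 10 libraries, with points for libraries and a line for the group mean of TPM + 1 on a log axis. LCN2 and IGF2 are high in the 3 knockout libraries alone, and REG4 is lower in knockout and higher in overexpression.

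The second comparison asked how PC3M-Luc-C6 cells labelled TRPV6 overexpression differed from unmodified cells. REG4, a secreted lectin gene, rose from 0.571 ± 0.181 to 26.4 ± 1.68 TPM (SD, n = 2 and 2), a log2 fold change of 4.13 ± 0.159 (SE; adjusted p = 3.95e-07, limma). PLAT, which encodes tissue plasminogen activator, rose from 16.8 ± 0.253 to 162 ± 0.814 TPM, the vasoactive peptide gene UTS2 from 4.08 ± 1.04 to 41.6 ± 2.32 TPM, and the surface protein gene CD24 from 8.33 ± 0.506 to 69.0 ± 2.24 TPM. TNFAIP6 and FAM133A rose by 2.24 and 1.90. FABP6, a bile acid-binding protein gene, went from 15.4 ± 0.196 to 2.94 ± 0.257 TPM, and ZP3, NKD2, DHRS2, HMGN5, RPRML and ARMCX6 fell by 1.90, 1.63, 1.37, 1.27, 1.22 and 1.21.

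The integrated stress response list rose here. Of 24 members 12 rose and none fell (16 adjusted over the list alone), with a median of 0.53 (adjusted p = 1.69e-08; adjusted p = 0.33 with an estimated correlation). VLDLR rose from 1.1 ± 0.0481 to 4.85 ± 0.00495 TPM and CEBPG by 0.50. ASNS stood at 92.8 ± 3.74 and 180 ± 1.77 TPM and did not pass (adjusted p = 0.072), though it did with each line fitted alone (adjusted p = 0.00058) and without wild-type PC-3M library 2 or 3 (adjusted p = 0.035 and 0.00099). ATF4 rose by 0.42 ± 0.113 (SE; adjusted p = 0.044), with values of 0.25 without overexpression library 2 (adjusted p = 0.29) and 0.19 ± 0.133 without the 2 libraries high in 5_8S_rRNA (adjusted p = 0.60). It did not pass with each line fitted alone, without the filter or with a term for the 5_8S_rRNA classes given below (adjusted p = 0.11, 0.13 and 0.060). Of 13 cancer testis genes 6 rose and none fell (8 adjusted over the list alone), and this was the only list that passed with an estimated correlation (adjusted p = 2.02e-08, and 0.023 as the adjusted p with an estimated correlation). MAGEC2 rose by 2.02 and MAGEA1 by 1.81.

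The matrix and mesenchymal lists passed as lists, with most of their members not passing singly. Of 24 matrix protease and inhibitor genes 6 rose and none fell (7 adjusted over the list alone; adjusted p = 0.010, and adjusted p = 0.41 with an estimated correlation), with the cathepsin B gene CTSB up by 0.47. Of 21 mesenchymal genes 3 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.48 with an estimated correlation). The cadherin gene CDH11 went from 12.2 ± 0.226 to 72.4 ± 10.8 TPM and CDH2 rose by 0.93, whereas SPARC and COL1A1 fell by 0.72 and 0.73. Of 18 bone metastasis genes 5 rose and 1 fell, also over the list alone (adjusted p = 0.0060, and adjusted p = 0.33 with an estimated correlation), with the Notch target gene HEY1 up by 1.83. Of 9 basal and squamous genes 4 rose, also over the list alone (adjusted p = 0.0060, and adjusted p = 0.44 with an estimated correlation), among them DSC3 and SERPINB5 by 0.80 and 0.72. The G2 and mitosis list passed with 2 of 30 genes higher, also over the list alone (adjusted p = 0.048, and adjusted p = 0.85 with an estimated correlation).

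Interferon response genes fell in 7 of 28 cases and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.41 with an estimated correlation). IFIT1 and ISG15 fell by 0.81 and 0.45 and ISG20 rose by 0.58. Cholesterol synthesis genes fell in 4 of 25 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0028, and adjusted p = 0.85 with an estimated correlation). HMGCS1 fell by 0.60 and SC5D rose by 0.34. The calcium lists did not pass: 3 of 18 extrusion and buffering genes rose (4 adjusted over the list alone), with RCN1 and CALM3 up by 0.47 and 0.49, and 1 of 22 entry and store release genes fell, also over the list alone. In the window of 25 neighbouring genes that holds CALM3, 10 genes rose and 0 fell, with a median of 0.35. Of 19 calcineurin and NFAT genes 1 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.56). Of 10 TRP channel genes 1 fell (3 adjusted over the list alone; camera adjusted p = 0.096).

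In total 1329 genes (9.14%) changed, 789 higher and 540 lower, and 153 of them at least 2-fold. The count was 382 without unmodified library 1, 509 without unmodified library 2, 440 without overexpression library 1 and 434 without overexpression library 2. Unmodified library 1 and overexpression library 2 stood at 2723 and 2254 TPM of 5_8S_rRNA, a ribosomal RNA, against 371 and 134 TPM in the other 2 libraries of the line: without that pair 103 genes passed, and with the rRNA class as a term 987 did. Without the pair, with 1 library left per group, calls ended for NKD2, HMGN5, RPRML, RCN1, CALM3, CTSB, IFIT1, ISG15, CEBPG, DSC3, SERPINB5, BOP1, SPARC, COL1A1, ISG20, SC5D, HMGCS1 and ATF4 (adjusted p up to 0.60). The SE of each was larger in that fit, and the log2 fold changes were 0.713 to 1.11 times those with all libraries, or 0.454 times for ATF4. Leaving out any 1 of the line's 4 libraries ended the calls of COL1A1, ISG20, SC5D and HMGCS1, with adjusted p up to 0.14, 0.16, 0.25 and 0.15. Those of ISG20 and SC5D also ended after median-of-ratios scaling (adjusted p = 0.057 and 0.066) and with the rRNA term (adjusted p = 0.056 and 0.052), and that of SC5D without PC-3M knockout library 2 (adjusted p = 0.054). Without the filter those of SPARC, COL1A1, ISG20, SC5D and HMGCS1 ended (adjusted p = 0.071, 0.065, 0.10, 0.093 and 0.091). Leaving out unmodified library 1 or overexpression library 1 ended those of SPARC, ISG15 and CEBPG, with adjusted p up to 0.15, 0.057 and 0.061. That of ATF4 ended without either unmodified library or overexpression library 2 (adjusted p up to 0.29), and also without PC-3M wild-type library 1 or 2 or knockout library 2. Without unmodified library 2, 5 of the 9 lists still passed, and the bone metastasis, G2 and mitosis, matrix protease and mesenchymal lists did not (adjusted p = 0.076, 0.052, 0.063 and 0.12). The G2 and mitosis list also did not pass without unmodified library 1, overexpression library 1 or wild-type PC-3M library 1 or with a pseudocount of 0.1 (adjusted p = 0.14, 0.30, 0.059 and 0.056), nor the mesenchymal list without overexpression library 2 (adjusted p = 0.051).

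**Figure D2:**
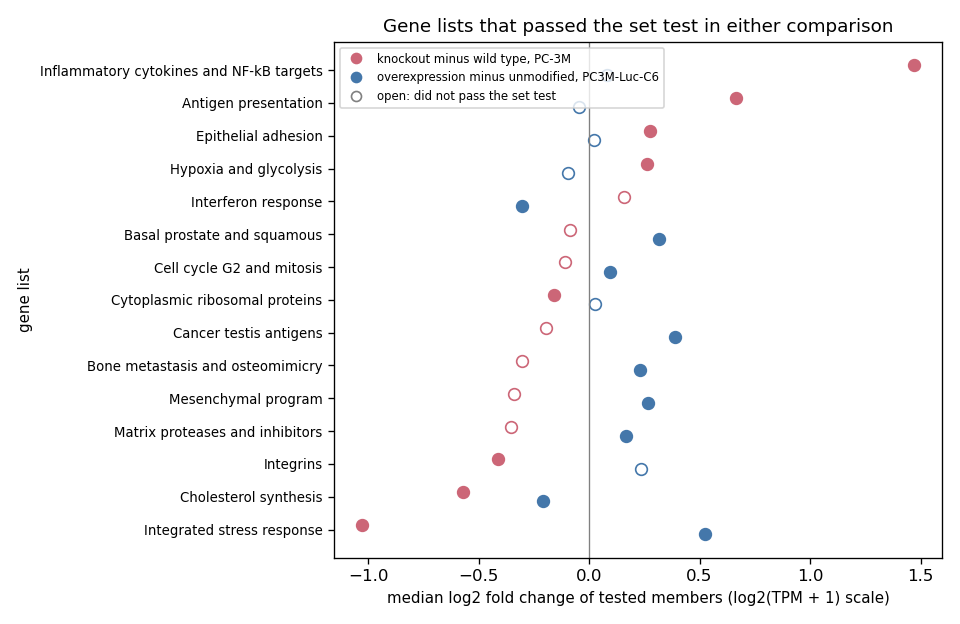
Points give the median log2 fold change of each list's tested members in both comparisons, filled where camera passed at an adjusted p under 0.05. The integrated stress response list lies at -1.03 in knockout and 0.53 in overexpression.

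The third comparison asked whether the changes in the 2 lines mirrored each other, since the modifications are labelled as opposite. Genes that fell in knockout and rose in overexpression numbered 370, against 199.1 expected for independent lists (odds ratio 2.80, Fisher's exact p = 9.11e-42), and genes that rose in knockout and fell in overexpression 188, against 104.8 (odds ratio 2.31, p = 1.05e-17, Fisher's exact test). Genes higher in both numbered 174 against 153.1 (p = 0.058, Fisher's exact test) and lower in both 118 against 136.3 (p = 0.069, Fisher's exact test). Fisher's test takes genes as independent, yet changes grouped along the chromosomes in both comparisons, as described below. From 40230317 to 42081552 on chromosome 19, 15 of 25 genes fell in knockout and 14 rose in overexpression, with none the other way in either. These p-values therefore do not measure how unlikely the overlaps are. Across genes, which are not independent replicates, the fold changes correlated at a Spearman rho of -0.093. REG4 fell by 3.94 in knockout and rose by 4.13 in overexpression. TSPAN8, ALDH1A2, MKX and the complement regulator gene CD59 likewise fell by 1.21, 0.78, 1.05 and 0.93 in knockout and rose by 1.63, 1.85, 1.86 and 0.81. In the reverse direction FABP6, HCLS1, DNAAF3, RASL11A and the ribosome biogenesis gene BOP1 rose by 1.19, 0.99, 0.87, 1.31 and 1.47 in knockout and fell by 2.06, 2.00, 0.73, 0.74 and 0.62 in overexpression. The 558 opposite genes became 185 to 228, and the 292 same-direction genes 78 to 104, when any 1 of the 4 PC3M-Luc-C6 libraries was left out.

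Line and type of modification went together in this design, so a difference between the changes cannot be assigned to either alone. The change from lower to higher labelled TRPV6 differed between the lines for 3883 genes, 2054 of them with the larger value in PC-3M and 1829 with the smaller. After median-of-ratios scaling this split was 1663 and 2259. Without overexpression library 1 the count was 2500. The unmodified lines differed at 7124 genes, 2336 higher and 4788 lower in PC3M-Luc-C6, and 1288 at least 2-fold. Median-of-ratios scaling moved the median of all genes in that comparison from -0.15 to 0.0099 and the split to 3708 higher and 3210 lower, so the direction of small differences between the lines depends on the scaling.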

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

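The tests on the genes beside TRPV6 were chosen only after that result was seen. The effect of higher labelled TRPV6 differed between the lines for 3883 genes by the interaction test (limma), and the named genes among them are given here as the change in PC-3M minus that in PC3M-Luc-C6, on the log2 scale.

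The difference was below 0, that is, a less positive or more negative change with higher labelled TRPV6 in PC-3M, for LCN2 (-9.30), C3 (-6.66), CXCL1 (-6.65), TRIM31 (-6.33), CCL20 (-6.08), CXCL6 (-5.59), IGF2 (-5.40), SNPH (-5.10), TRBC2 (-4.33), MAGEC2 (-3.94), FAM133A (-3.88), TNFAIP6 (-3.55), CD24 (-3.49), CDH11 (-2.97), PLAT (-2.76), HEY1 (-2.27), TRBC1 (-1.95), HLA-B (-1.94), MAGEA1 (-1.61) and CTSB (-1.56). Smaller differences of that sign were found for CALB2 (-1.501), EPHB6 (-1.44), KRT7 (-1.18), HOMER2 (-1.11), ALDH1A2 (-1.07), ORAI1 (-1.02), CDH2 (-0.997), TNFRSF9 (-0.99), PSMB8 (-0.97), DSC3 (-0.91), CA12 (-0.91), BOP1 (-0.85), MKX (-0.80), EPCAM (-0.66), ISG20 (-0.57), RASL11A (-0.56), PFKP (-0.42) and RCN1 (-0.40).

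The difference was above 0 for SPANXA2 (8.97), TCN1 (6.23), PHACTR3 (5.998), GAGE12F (5.50), GAGE2E (5.30), SPANXA1 (5.25), TFF3 (5.11), GAGE12G (4.86), SPARC (4.32), CCL2 (2.58), RCAN2 (2.48), PIEZO2 (2.36), ITGB8 (2.28), ZP3 (2.18), HMGCS1 (1.85), ASNS (1.81), ICAM1 (1.66), NUPR1 (1.60) and LSS (1.502). Smaller differences of that sign were found for DHRS2 (1.45), HMGN5 (1.40), ITPR2 (1.15), HCLS1 (1.01), NKD2 (0.95), SLC8A1 (0.94), NFATC2 (0.90), FABP6 (0.87), SESN2 (0.87), ARMCX6 (0.76), SREBF2 (0.64), ITGB1 (0.59), VEGFA (0.59), ATF4 (0.58), RPL10 (0.51), CLDN4 (0.42), RPS6 (0.35) and ISG15 (0.32).

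A first pattern lies beside TRPV6. In the overexpressing libraries TRBC2 (chromosome 7, 142801041 to 142802748) stood at 27.9 ± 1.86 TPM (SD, n = 2) and TRBC1 (142791694 to 142793368) at 2.88 ± 0.445, both listed at 0 in unmodified cells, and EPHB6 (142855061 to 142871094) rose by 1.63 ± 0.205 (SE). Without the 2 libraries high in 5_8S_rRNA, which leaves 1 library per group in this line, EPHB6 did not pass (1.55 ± 0.326, adjusted p = 0.094). T cells are argued against, since the median of CD3D, CD3E, CD3G, CD2, PTPRC and TRAC was 0% of the TRBC2 level, with TRAC highest at 0.21 TPM. More mRNA counted at TRPV6 itself is argued against, since TRPV6 reached 0.036 TPM at most. A chance run stays open: with the near-identical TRBC1 and TRBC2 counted as 1, a share of 0.000988 of 13164 other genes had as many genes risen at least 2-fold within 100 kb, but place and number were taken from the run itself. No biological explanation was tested for these genes.

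A second pattern is the grouping of the knockout changes along the chromosomes. The SD of mean changes over 384 windows of 25 neighbouring genes was 1.92 times its median after shuffling gene order, as a copy-number difference between the cells would give. The ratio was also 2.22 in overexpression, and neighbouring genes regulated together could give it too, so it does not single out copy number. For the 16 largest single changes, the test of a copy-number difference shared by the 24 nearest expressed genes cannot decide. Those neighbours showed a median of 0.015 of the change, and 0.0906 at most (CXCL6). No window median lay further than 0.891 from 0, while these genes were picked for changes of at least 4.66. The highest share that any window allowed was therefore 0.191, so a share under the bound of 0.2 was fixed in advance. A copy-number change of fewer genes, such as a loss of 1 gene alone, would leave the neighbours unmoved and stays open. For the windows a copy-number difference stays open. At the start of chromosome 5 (218303 to 10307902) 21 of 25 genes were lower, with a median of -0.89. Shifts also ran over neighbouring windows. On chromosome 7, 25 of 25 genes were lower from 549197 to 5040675. From 43866558 to 51316818 on it 19 of 25 were lower and none higher, and the windows between had medians below 0. The median change was -0.31 over chromosome X and 0.22 over chromosome 14.

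The last pattern is the fall of the integrated stress response list in knockout and its rise in overexpression. Scaling is argued against, since it moves all genes of a library about alike, and the list medians were still -0.9525 and 0.5288 after median-of-ratios scaling, with 0.5286 the nearest to 0 under either other scaling. A single library is argued against, since with any 1 library of a comparison left out the list median stayed at least 0.53 from that of all genes. The list mean then differed least without overexpression library 2, by 0.45. A difference in culture state between plates cannot be told apart from the groups: the nearest libraries of 2 groups were 0.426 apart in the list's mean, so the groups did not overlap, but the labels give no plate or day, so a state shared by all plates of a group would look the same. The labelled TRPV6 difference stays open as well. The list also differed between the lines without a labelled modification. Its mean was 5.402 and 5.45 (log2) in unmodified PC3M-Luc-C6, against 6.242 to 6.453 in wild-type PC-3M and 5.28 to 5.323 in knockout.

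The 6492 genes changed in knockout were compared with other groupings of the 6 PC-3M libraries. As 3 against 3 makes 10 splits, a share under 0.05 cannot be reached. The real split was the 1 with as many, and the highest of the others gave 1 gene. Every other split mixed knockout and wild-type libraries in both groups. The knockout difference then counted as spread within groups, so few calls were likely from the start.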

How the results depend on the processing

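The 2 fits on the 5_8S_rRNA classes and the rescaling without mitochondrial and structural RNA were chosen only after the data were seen. Of 104 named results, 20 lost their call under at least 1 alternative and 0 of 1968 values reversed. Most of these results had been picked because they passed, and several alternatives leave an estimate unchanged, so reversals were unlikely from the start. PC3M-Luc-C6 overexpression gave 873 genes without the filter, 153 at a 2-fold minimum and 103 without the 2 libraries high in 5_8S_rRNA. Knockout gave 838 and the line difference 1288 at a 2-fold minimum. Without the high-rRNA pair the effect differed between lines for 1562 genes, the unmodified lines at 4480, opposite genes numbered 48 and same-direction genes 25. Without the filter these last were 321 and 151, and 182 same-direction genes with a pseudocount of 0.1 as well. Shifted lists in knockout numbered 13 without the filter, 14 with the pseudocount of 0.1 as well and 0 with an estimated correlation, where overexpression kept 1. Losses at a 2-fold minimum follow from its construction. Fewer libraries leave less to estimate the spread from, yet the knockout count rose to 6696 without knockout library 3. The causes of losses other than those at a 2-fold minimum were not tested. With 1 library left out, where a lone sample is assumed to vary like the other groups, overexpression ranged from 382 to 1602 genes, the difference between lines from 2500 to 4373, opposite genes from 185 to 630, same-direction genes from 78 to 375 and shifted lists in overexpression from 5 to 10. The replicate block gave 7102 genes in knockout, 1507 in overexpression, where ASNS passed (adjusted p = 0.044), and 4472 for the difference. Deviations of same-numbered libraries correlated at 0.0998, -0.142 and 0.236 in PC-3M and 0.0774 in PC3M-Luc-C6, and not every PC-3M library correlated best with its own number, so the numbers were not taken to pair the samples. The count models planned for counts were not run on TPM. Depth is unknown.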

Other observations

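Of 35 lists tested, 27 did not pass the set test in knockout, and those not described above follow. Of 12 S100 genes 7 fell and 1 rose (adjusted p = 0.25), of 24 matrix protease and inhibitor genes 12 fell and 4 rose (adjusted p = 0.076), and of 21 mesenchymal genes 8 fell and 2 rose (adjusted p = 0.25), none shifted as a list by camera. Of 30 G2 and mitosis genes 11 fell and 2 rose (adjusted p = 0.44), and of 28 interferon response genes 7 rose and 3 fell (adjusted p = 0.053). Of 31 apoptosis genes 10 rose and 5 fell (adjusted p = 0.076), of 30 S phase genes 7 and 5 (adjusted p = 0.14), of 20 ER chaperone genes 7 and 4 (adjusted p = 0.16) and of 13 mitochondrial transcripts 1 and 0 (adjusted p = 0.10). Genes that rose and fell numbered 4 and 5 of 14 for vitamin D response, 1 and 2 of 20 immediate early, 3 and 5 of 18 bone metastasis, 3 and 3 of 12 necroptosis and pyroptosis, and 6 and 6 of 22 p53 target genes. They numbered 6 and 6 of 19 Hedgehog, WNT and Notch genes, 2 and 6 of 21 YAP targets, 3 and 7 of 16 solute and potassium channel genes, 3 and 6 of 13 cancer testis genes and 0 and 2 of 15 histone genes. Of prostate genes they numbered 1 and 3 of 6 luminal, 3 and 3 of 6 neuroendocrine and 2 and 3 of 9 basal ones (adjusted p of 0.37 or higher for these lists). Markers of other cell types were few: 5 fibroblast genes were tested, of which 3 fell, and 4 endothelial and 2 leukocyte genes, too few for the set test. In overexpression 26 of the 35 lists did not pass, the lowest adjusted p among them being 0.096 (TRP channels and integrins). None of 25 cytokine and NF-kB target genes passed the test (adjusted p = 0.72 for the list).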
